A study of Mus musculus with 12 samples.

How the data were processed

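Total RNA of the cerebellum was extracted with TRIzol and labelled with the Affymetrix GeneChip WT Terminal Labeling kit, per the labels' protocols. The samples are 6 arrays, 3 from wild-type and 3 from NMF291–/– female mice at postnatal day 30, each deposited once at gene level and once at exon level. The 2 tables are therefore 2 summaries of the same arrays and were tested apart, never as 6 replicates. The deposited values are on a log scale taken here as log2, from their range of about 2.32 to 14.5 on a 16-bit scanner. Background correction, normalization and summary method are not given in the sources used here, and the genome build is mm8 per the submitters' processing notes. The authors' unstated normalization could change differences between arrays, which is why quantile normalization and median centring were run as alternatives. No column of either table was left unused.

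The gene-level table has 23332 rows. Of these, 16755 carry a transcript cluster ID and 6577 carry the ID of a probe set and hold the exon-level table's values unchanged. Gene names came from the platform annotation and were updated through a RefSeq table of assembly GRCm38.p6, which was used for names and chromosomes only. At gene level, 14996 rows have 1 symbol (14847 genes), 1019 have several and 7317 are unnamed here. At exon level, 209279 of 229581 probe sets have 1 symbol (16358 genes, median 11 probe sets per gene), 4446 have several and 15856 are unnamed here. No gene was named from a row with several symbols. Of 148 genes with several transcript clusters, none had clusters passing in opposite directions. Positions of the probe sets in their genes were not analysed here, so a changed probe set is not assigned to an exon number or type. The labels name the mutated gene Rnu2-8; its level was not analysed here.

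Differences are mutant minus wild type. They were tested with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3 with no covariate, Benjamini-Hochberg adjustment over all rows of a table and a threshold of 0.05 on the adjusted p, with no filter on low values. Arrays give no counts, so depth has no meaning here and the number of arrays sets the precision. For exon usage, the splicing index was tested for probe sets with 1 gene symbol, in genes with at least 3 probe sets whose gene median was at or above the 50th percentile of the table (8.55) and for probe sets at or above the 25th percentile (7.06). A probe set that is its gene's median has an index of exactly 0, which can make its spread too small. A gene list was tested with camera and a preset inter-gene correlation of 0.01, on the transcript cluster with the highest mean per gene (14847 genes), with an estimated correlation and fry beside it; 41 lists of cell types, neighbouring tissues, splicing, stress, immune, neuronal and housekeeping genes were fixed before the data were examined. fry tests whether a list's genes move one way on balance and compares no list with other genes. Exon usage in lists was tested with Fisher's exact test, two-sided, beside 10000 random lists matched on probe set number; for diffSplice calls the matched lists were added after seeing the data.

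The genes named were fixed by a rule: among rows with 1 symbol, an adjusted p under 0.05 and no overlap of the groups' values, the 10 largest rises and the 10 largest falls; up to 4 members of each list with the smallest p; and 10 probe sets in each direction by splicing index, 1 per gene, filled by the smallest p where fewer passed and then stated as not passing. The U2 snRNA gene was to be named where annotated.

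The scripts were tested on simulated arrays with the real rows' means and spread and 200 changed rows. For gene-level rows, over 23332, 51 of 100 changes of 0.5 and 80 of 100 changes of 1 (log2) were recovered, with 8 false calls among 139. For probe sets changed, over 229581 rows, 0 of 100 changes of either size were recovered by limma. For exon usage, over 107238 probe sets, diffSplice recovered 62 of 100 changes of 0.5 and 100 of 100 changes of 1, with the false calls given beside its result. For gene lists, over 14847 genes, 5 of 5 lists shifted by 0.2 were recovered by camera with the preset correlation, 4 with an estimated correlation and 4 by fry, with 0 false calls among 32 lists; simulated genes were independent, unlike real ones.

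Alternatives were the replicate number as a block, a filter on low values, eBayes with trend and robust settings, quantile normalization, median centring, array weights, an adjusted p under 0.1, leaving out each array, leaving out chromosome 11, other gene levels for the splicing index and diffSplice. Chosen after seeing the data were tests on transcript clusters only, the median of a gene's other probe sets as its level, leaving out the genes of the 2 microglia lists, and matched random lists for diffSplice calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.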

Results

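Cerebellar total RNA from 6 female mice at postnatal day 30 was hybridised to 6 Affymetrix Mouse Exon 1.0 ST arrays, 1 mouse per array. Of these mice, 3 were wild type and 3 were NMF291–/–, which carry a deletion of 5 nucleotides in a gene for U2 snRNA. U2 snRNA is the spliceosome component that pairs with the branch site of an intron. Each array was deposited at gene level, as 23332 rows of which 16755 are transcript clusters and 6577 single probe sets, and at exon level, as 229581 probe sets. The series text calls the mice of each genotype biological replicates. Gene-level medians were 8.00 to 8.03 (log2) on the wild-type arrays and 8.05 to 8.09 on the mutant arrays. Over all gene-level rows, arrays of one genotype correlated at 0.992 to 0.994 and arrays of different genotypes at 0.988 to 0.991, across rows that are not independent. The number of arrays, 3 per genotype, limits the precision of every value. No row of either table is named for a U2 snRNA gene, so the mutated gene itself was not analysed here.

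The first comparison asked which genes differ in level between the mutant and wild-type cerebellum. A gene-level value summarises a gene's probe sets, so unequal changes among them can also move it. Genes expressed by microglia and by reactive astrocytes were among the largest rises. Ccl3, a chemokine made by activated microglia and macrophages, rose from 7.14 ± 0.26 in wild type to 9.73 ± 0.35 in the mutant (log2, SD, n = 3), a 6.03-fold rise with an adjusted p of 0.00801 by limma. Gfap, the intermediate filament protein of astrocytes, rose by 1.48 ± 0.22 (log2, SE; adjusted p = 0.0272). Among the 10 largest falls, Cadps2, which primes dense-core vesicles for release, was at 10.86 ± 0.05 in wild type and 9.90 ± 0.09 in the mutant (SD, n = 3), and Rims3, a member of the RIM family of active-zone proteins, was at 10.38 ± 0.05 and 9.44 ± 0.05; their adjusted p-values were 0.00483 and 0.00384.

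The other genes among the 10 largest rises were Mtfr2, a regulator of mitochondrial fission, at 3.22-fold, Ly86 at 3.15-fold and its binding partner Cd180 at 3.03-fold. They were joined by the surface protein Cd52 at 3.11-fold, the lysosomal protein Cd68, which rose by 1.58 (log2), the Fc receptor-like gene Fcrls at 2.98-fold, the complement component C1qb at 2.92-fold and the signalling adaptor Tyrobp at 2.79-fold. Adjusted p-values of these 8 genes ran from 0.00801 for Mtfr2 to 0.0369 for Cd52. The largest fall was that of Sptssb, a small subunit of serine palmitoyltransferase, to 0.474 of its wild-type level (adjusted p = 0.00891). Fstl5 was at 0.498 of its wild-type level, the hormone-degrading enzyme Trhde at 0.514, Vwa7 at 0.520, the ryanodine receptor Ryr3 at 0.525, the taste receptor Tas2r135 at 0.546, Phxr4 at 0.546 and the transporter Abca8b at 0.561. Of the falls, the highest adjusted p was 0.0217, for Tas2r135. In all 20 of these genes every mutant array lay on one side of every wild-type array, which the rule that chose them required.

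**Figure D1:**
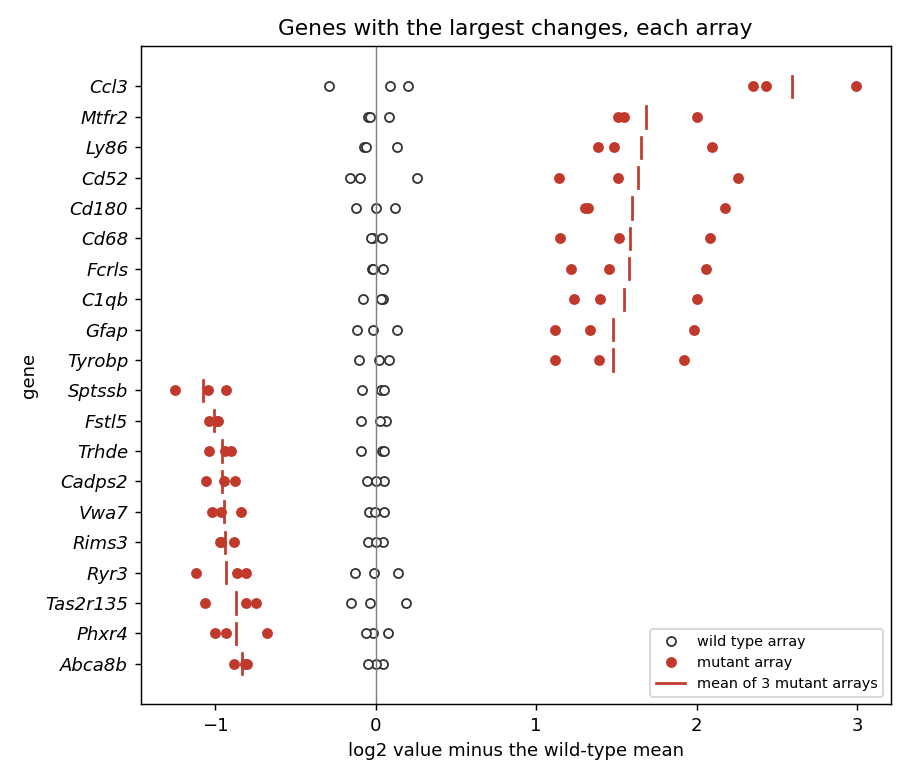
The horizontal axis is each array's log2 value minus the wild-type mean of that gene, for the 10 genes with the largest rise and the 10 with the largest fall. Open points are the 3 wild-type arrays, filled points the 3 mutant arrays and bars the mutant means, which run from 2.59 for Ccl3 to -1.08 for Sptssb; mutant replicate 2 has the highest value of the mutants for each of the 10 rising genes.

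Over the whole gene-level table, 1342 of 23332 rows changed, 920 higher and 422 lower in the mutant. The share of higher calls, 68.6%, depended on the scaling: after median centring of the arrays 529 of 1129 calls (46.9%) were higher and 600 lower, and after quantile normalization 680 of 1275 (53.3%) were higher and 595 lower. Of the 14996 rows with 1 gene symbol, 627 rose and 346 fell. Of the changed rows 51 moved by 1 or more on the log2 scale, 48 of them upwards. Each left-out array lowered the count: 496 rows passed without wild-type replicate 1, 162 without wild-type replicate 2, 167 without wild-type replicate 3, 87 without mutant replicate 1, 159 without mutant replicate 2 and 76 without mutant replicate 3. At the exon level 2307 probe sets changed, 1384 higher (60.0%) and 923 lower. After median centring 1128 probe sets were higher (50.9%) and 1088 lower, and after quantile normalization 1222 were higher (54.0%) and 1040 lower. With any array left out the limma count was 0, beside 31235 to 39930 probe sets at an unadjusted p under 0.05.

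Lists said below to rise, fall or shift were called by camera with the preset correlation. That test also called 3 to 15 of the 41 lists when the arrays were grouped across genotypes. A call by this test alone is therefore not enough to show a difference between genotypes. Such groupings still hold unequal shares of mutants, so these counts are not a rate of false calls. Microglia genes rose as a group. Of 21 microglia and macrophage markers measured, 13 rose, none fell and 8 did not pass, with 19 rising when adjusted over the list alone. Their mean change was 0.85 (log2; camera adjusted p = 5.18e-12, and adjusted p = 0.507 with an estimated correlation). Ly86, Cd53 (1.89-fold), C1qb and Fcrls had the smallest p-values. Of 20 activated microglia genes 6 rose and none fell, 11 when adjusted over the list alone, led by Ccl3, Cd68, Cd52 and the lipoprotein lipase gene Lpl, which rose by 0.64 ± 0.12 (SE). The mean change of that list was 0.59 (camera adjusted p = 7.59e-06, and adjusted p = 0.549 with an estimated correlation). The 3 mutant arrays had microglia list means of 0.62, 1.17 and 0.75 above the wild-type mean. Beside them, the blood cell list had a mean change of -0.002 and the meningeal list one of -0.03, and neither passed.

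The reactive astrocyte, complement and interferon lists shifted upwards with smaller changes. Of 23 reactive astrocyte genes 2 rose, Gfap and the protease inhibitor Serpina3n (2.40-fold), and 3 when adjusted over the list alone; Osmr at 0.40 and Timp1 at 0.74 (log2) did not pass (camera adjusted p = 0.0257, and adjusted p = 0.584 with an estimated correlation). That call was lost without wild-type replicate 2 (adjusted p = 0.0686). Of 18 complement and inflammatory genes 4 rose, both over all genes and adjusted over the list alone. They were C1qa, C1qb and C1qc, which the microglia list also holds, and Ccl5 (camera adjusted p = 0.0273, and adjusted p = 0.507 with an estimated correlation). The complement call was lost without wild-type replicate 1 (adjusted p = 0.0634). None of 25 interferon response genes passed on its own, by either adjustment, while 24 had a positive change. The viral RNA sensor Ddx58 was at 0.64 ± 0.16 (SE) and the transcription factors Irf9 and Stat2 at 0.35 and 0.18 (camera adjusted p = 0.00449, and adjusted p = 0.660 with an estimated correlation). Means of the interferon list in the 2 genotypes overlapped, at 0.09, 0.43 and 0.13 in the mutants against a wild-type range of -0.10 to 0.11.

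The 2 lists of snRNP and spliceosome proteins shifted upwards. Of 22 genes for U2 snRNP proteins and their partners, 7 rose and none fell, 10 when adjusted over the list alone, and 21 had a positive change. Sf3b3 rose by 0.59 ± 0.04, Sf3a2 by 0.66 ± 0.07, Sf3b4 by 0.56 ± 0.07 and Snrpa1 by 0.44 ± 0.04 (log2, SE); all are components of the U2 particle. The list mean was 0.22 (camera adjusted p = 7.05e-07, and adjusted p = 0.367 with an estimated correlation). Of 30 genes for other snRNP and spliceosome proteins 9 rose and none fell; adjusted over the list alone 18 rose and 1 fell. Prpf3 rose by 0.59 ± 0.04, the helicase Snrnp200 by 0.46 ± 0.04, Xab2 by 0.46 ± 0.05 and Sart1 by 0.45 ± 0.05 (camera adjusted p = 9.37e-07, and adjusted p = 0.502 with an estimated correlation). The 3 mutant arrays were close for both lists, at 0.21 to 0.23 for the U2 list and 0.18 to 0.19 for the other.

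The lists of RNA surveillance, of the integrated stress and unfolded protein response and of the cell cycle also shifted upwards. Of 20 nonsense-mediated decay and RNA surveillance genes, Upf1, the helicase of nonsense-mediated decay, rose by 0.30 ± 0.04 and the exosome nuclease Exosc10 by 0.21 ± 0.04, and both passed when adjusted over the list alone; Smg9 and Xrn1, at 0.18 and 0.16, did not pass (camera adjusted p = 0.00627, and adjusted p = 0.367 with an estimated correlation). Of 34 integrated stress and unfolded protein response genes 4 rose, 7 when adjusted over the list alone: Mthfd2 by 0.39, Asns by 0.29, Edem1 by 0.32 and Cebpg by 0.32 (camera adjusted p = 0.0226, and adjusted p = 0.660 with an estimated correlation). That list's call was lost without wild-type replicate 2 (adjusted p = 0.129) or 3 (adjusted p = 0.0514). Its means in the 2 genotypes overlapped, at 0.04, 0.10 and 0.10 in the mutants against a wild-type range of -0.04 to 0.06. Of its members 24 had a positive change and 10 a negative one, among the latter the unfolded protein response genes Xbp1 at -0.17 and Sdf2l1 at -0.18, which did not pass. Of 19 cell cycle genes 4 rose, the replication helicase subunit Mcm5 by 0.96 ± 0.05, Plk1 by 0.37, Ccna2 by 0.46 and Mcm2 by 0.32. Adjusted over the list alone 6 rose and 1, Ccnd1 at -0.32, fell (camera adjusted p = 0.0117, and adjusted p = 0.507 with an estimated correlation). In that list 14 members had a positive change and 5 a negative one, with Mki67 at 0.01 and Birc5 at -0.005. Proliferation itself was not measured.

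Neuronal lists shifted downwards. Of 25 presynaptic release genes 6 fell and none rose, 13 when adjusted over the list alone. The priming factor Unc13c fell by 0.58 ± 0.06, the active-zone proteins Rims1 and Rims2 fell by 0.44 ± 0.06 and by 0.39 ± 0.05, and the fusion ATPase Nsf fell by 0.26 ± 0.04 (SE; camera adjusted p = 7.05e-07, and adjusted p = 0.507 with an estimated correlation). Of 29 voltage-gated ion channel genes 6 fell and none rose, 11 when adjusted over the list alone, among them the calcium channel Cacna1c at -0.43 and the potassium channels Kcnd2 at -0.46, Kcna1 at -0.31 and Kcnq3 at -0.42 (camera adjusted p = 7.05e-07, and adjusted p = 0.367 with an estimated correlation). Of 29 glutamate receptor and scaffold genes 3 fell, the postsynaptic scaffold Dlg4 at -0.38, Grik2 at -0.41 and Cbln2 at -0.37, and the NMDA receptor subunit Grin2c rose by 0.33; adjusted over the list alone 6 fell and 1 rose (camera adjusted p = 4.19e-04, and adjusted p = 0.367 with an estimated correlation). The Grin2c call was lost under both other scalings, where 7 genes of this list fell and 0 rose after quantile normalization and 6 fell and 0 rose after median centring.

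Of 14 inhibitory synapse genes 2 fell by either adjustment, the GABA receptor subunit Gabra6 at -0.46 and the chloride transporter Slc12a5 at -0.30, while Glra3 at -0.12 and Gphn at -0.14 did not pass (camera adjusted p = 0.00922, and adjusted p = 0.552 with an estimated correlation). Of 25 cytoskeleton and axon genes 2 fell, Dst at -0.32 and Clasp2 at -0.27, and 4 when adjusted over the list alone; Dync1i1 at -0.24 and Epb41l3 at -0.16 did not pass over all genes (camera adjusted p = 0.00118, and adjusted p = 0.507 with an estimated correlation). Among 21 granule neuron markers 6 fell and 1, Grin2c, rose, a rise lost under both other scalings; adjusted over the list alone 9 fell and 2 rose. Cadps2 at -0.96, Gabra6 at -0.46, Kcnd2 at -0.46 and the extracellular protein Reln at -0.40 had the smallest p-values (camera adjusted p = 6.22e-04, and adjusted p = 0.584 with an estimated correlation). Gabra6 is also in the inhibitory synapse list, Kcnd2 in the ion channel list and Grin2c in the glutamate list, so these lists are not independent. The Purkinje list shares 4 listed genes with the glutamate list. None of 17 Purkinje cell markers passed by either adjustment, while all 17 had a negative change. Plcb4 was at -0.17, Gng13 at -0.27, Car8 at -0.12 and Ppp1r17 at -0.10 (camera adjusted p = 0.00383, and adjusted p = 0.584 with an estimated correlation).

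Markers of tissue next to the cerebellum were measured as well. None of 11 choroid plexus markers passed by either adjustment, although all 11 had a negative change, with Otx2 at -0.38, Calml4 at -0.62, Aqp1 at -0.27 and Steap1 at -0.25 (camera adjusted p = 0.0249, and adjusted p = 0.698 with an estimated correlation). That list rested on 1 array: its mean was -1.04 in mutant replicate 3 and -0.05 and -0.005 in the other mutants, and the adjusted p without mutant replicate 3 was 0.615. Without wild-type replicate 1 it was 0.118. None of 18 brainstem and hindbrain neuron markers passed by either adjustment, with Hoxa5 at -0.19, Hoxc4 at -0.16, Phox2a at -0.10 and Tph2 at -0.13 (camera adjusted p = 0.0257, and adjusted p = 0.507 with an estimated correlation). The brainstem call was lost without mutant replicate 2 (adjusted p = 0.0728) or wild-type replicate 3 (adjusted p = 0.0742). In all, camera with the preset correlation called 19 of 41 lists, 10 up and 9 down, and none with an estimated correlation, where 4 lists had an unadjusted p under 0.05; fry called 12.

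Among rows at or above the table median, 12 of the 19 calls were kept. Lost there were the reactive astrocyte (adjusted p = 0.246), interferon (0.113), complement (0.0533), stress response (0.162), cell cycle (0.842), choroid plexus (0.102) and brainstem (0.785) lists. Of the list members named as passing, Grin2c, C1qc, Rbm39 and Exosc10 passed under neither quantile normalization nor median centring. Rbfox1 and Edem1 did not pass under quantile normalization, and Srsf11, Hnrnpab, Cebpg, Mcm2 and Cyc1 did not pass under median centring. Calls were also gained: of the cytoskeleton and axon genes 3 fell after quantile normalization and 4 after median centring. There Dync1i1 passed under both scalings and Epb41l3 under median centring.

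**Figure D2:**
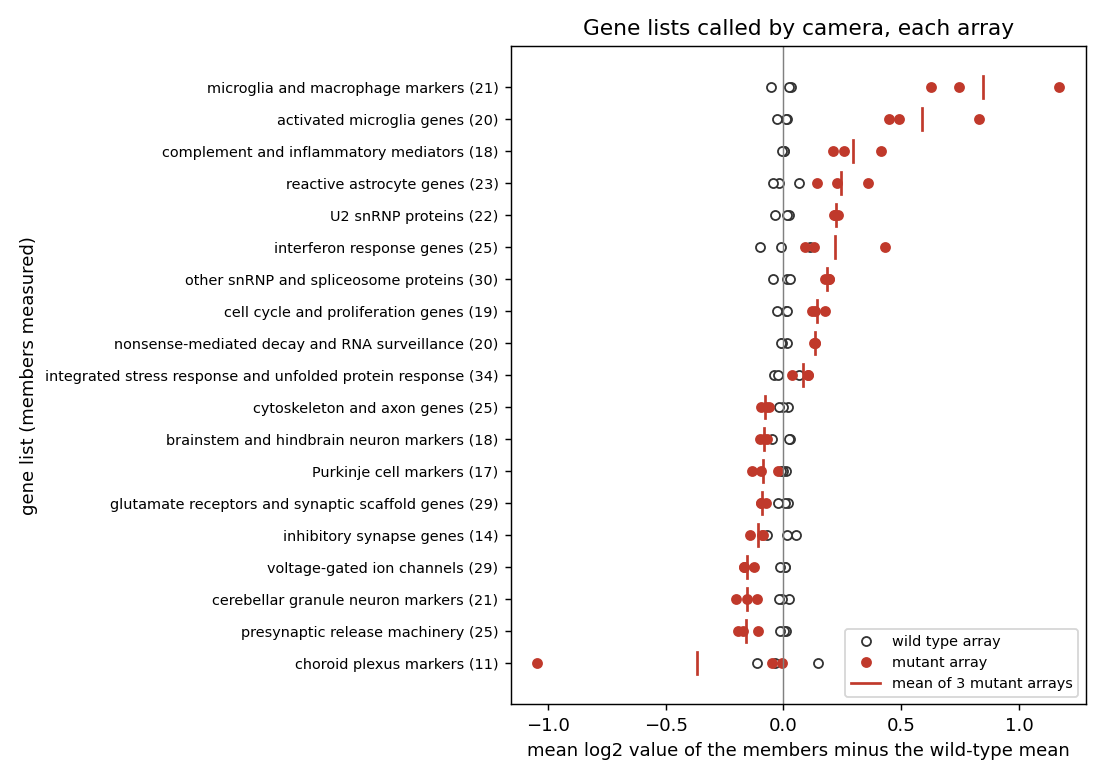
The horizontal axis is the mean log2 value of a list's members on each array minus the wild-type mean, for the 19 lists called by camera with the preset correlation. Open points are the 3 wild-type arrays, filled points the 3 mutant arrays and bars the mutant means, from 0.85 for the microglia markers to -0.37 for the choroid plexus markers, where mutant replicate 3 alone lies at -1.04; all 19 means keep their sign under quantile normalization and median centring.

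The remaining 22 lists were not called by camera. Among splicing regulators, Srsf11 rose by 0.26 and Rbm39 by 0.25 while Srsf5 fell by 0.35, of 26 SR proteins and SR-like regulators; adjusted over the list alone 2 rose and 7 fell (camera adjusted p = 0.320). In that list 1 rose and 2 fell after quantile normalization, and 0 rose and 2 fell after median centring. Of 38 hnRNPs and other regulators, Ptbp1, a repressor of neuronal exons, rose by 0.96 ± 0.06 and Hnrnpab by 0.20, and Sfpq fell by 0.29 and Rbfox1 by 0.22, with 5 up and 6 down when adjusted over the list alone (camera adjusted p = 0.862); 2 rose and 3 fell after quantile normalization, and 1 rose and 4 fell after median centring. Not all Ptbp1 probe sets followed that rise: 4407948 moved by 0.34 and 5540766 by -0.02, against 1.06 for the gene's median probe set. Of 19 immediate early genes, Jun fell by 0.48, Arc by 0.32 and Btg2 by 0.46, also when adjusted over the list alone (camera adjusted p = 0.0735). Btg2 was the 1 faller among 23 p53 targets (camera adjusted p = 0.290), where Sesn2 at 0.27 and Sesn1 at 0.24 did not pass over all genes; adjusted over the list alone 2 rose and 1 fell. Jun and Gadd45b, which fell by 0.66, were the 2 fallers among 19 apoptosis and axonal injury genes, where 3 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.761). The chaperone Hspa1a fell by 0.38, the 1 change among 12 heat shock genes by either adjustment (camera adjusted p = 0.0910).

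Of 25 oxidative phosphorylation genes, Cyc1 rose by 0.30, and none passed when adjusted over the list alone (camera adjusted p = 0.0735). Of 4 replication-dependent histone genes, H2aw fell by 0.26 by either adjustment (camera adjusted p = 0.154). Gfap was the 1 riser among 20 Bergmann glia and astrocyte markers by either adjustment, with Aqp4 at 0.33 not passing (camera adjusted p = 0.862). In the other lists no member passed by either adjustment. Their camera adjusted p-values were 0.0955 for 13 inhibitory interneuron markers, 0.481 for 5 unipolar brush cell markers, 0.317 for 18 oligodendrocyte and myelin markers, 0.605 for 10 oligodendrocyte precursor markers and 0.672 for 18 endothelial and vascular markers. They were 0.290 for 4 ependymal markers, 0.619 for 12 meningeal markers, 0.795 for 7 blood cell markers and 0.0815 for 15 forebrain and midbrain markers. They were 0.673 for 14 oxidative stress genes, 0.920 for 14 circadian clock genes, 0.912 for 15 cholesterol synthesis genes and 0.565 for 13 ribosomal protein genes. The median, the mean and the direction of the test differ in sign for the unipolar brush cell, Bergmann glia, endothelial, blood cell, SR protein, hnRNP and circadian lists. Under the other scalings, a fall of Cux2 in the forebrain and midbrain list passed after both quantile normalization and median centring. A fall of Msmo1 in the cholesterol list passed after quantile normalization only.

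The second comparison asked which exons are used differently within their gene. The splicing index of a probe set, its log2 value minus the median of its gene's probe sets on the same array, was tested for 107238 probe sets of 7264 genes. By limma, 9 probe sets in 7 genes changed, 7 higher and 2 lower in the mutant, beside 11944 probe sets at an unadjusted p under 0.05. That balance depended on the setting. At an adjusted p under 0.1, 50 were higher and 50 lower. Among probe sets at or above the table median 24 were higher and 27 lower, and with the mean of the probe sets as the gene's level 98 and 65. Nedd4l, a ubiquitin ligase, had 3 of the 9 passing probe sets, out of 36 tested. Its probe set 5542869 had a splicing index of 0.26 ± 0.02 in wild type and 1.71 ± 0.08 in the mutant (SD, n = 3), a 2.73-fold rise relative to the gene (adjusted p = 0.0188), while the gene's median probe set was at -0.32. Probe sets 4922703 and 5353744 of Nedd4l rose by 1.14 and 1.11 relative to the gene.

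In Tcf25 1 of 22 probe sets, 4648667, rose by 1.19 ± 0.05 (log2, SE; adjusted p = 0.0206), and in Ep400, a chromatin remodelling ATPase, 1 of 73, probe set 5264592, rose by 1.09 ± 0.06 (adjusted p = 0.0292). In Socs6, a suppressor of cytokine signalling, 1 of 5 probe sets rose by 1.34 ± 0.09 (adjusted p = 0.0474). Of these 5 probe sets 4 were higher relative to the gene and 1 lower, and 4, all higher, had an unadjusted p under 0.05. The Socs6 call therefore does not single out 1 probe set against an unchanged rest of the gene. In the active-zone gene Rims2, probe set 5571431 rose by 0.82 ± 0.05 relative to its gene (adjusted p = 0.0358), and probe set 4743899 was at -0.67 without passing (adjusted p = 0.0519); 21 of 35 Rims2 probe sets had an unadjusted p under 0.05. The falls were in the chaperone gene Hspa14, by 0.91 ± 0.06, and in Acvr1, a receptor for bone morphogenetic proteins, by 0.89 ± 0.05, both with an adjusted p of 0.0358. The Hspa14 probe set itself moved by -0.41, while its gene's median probe set moved by 0.49. The Acvr1 probe set was its gene's median on every wild-type array, so its wild-type SD is 0; it moved by 0.03 while its gene's median probe set moved by 0.92, and with the mean of the gene's probe sets as the gene's level its change was -0.17 (adjusted p = 0.429).

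**Figure D3:**
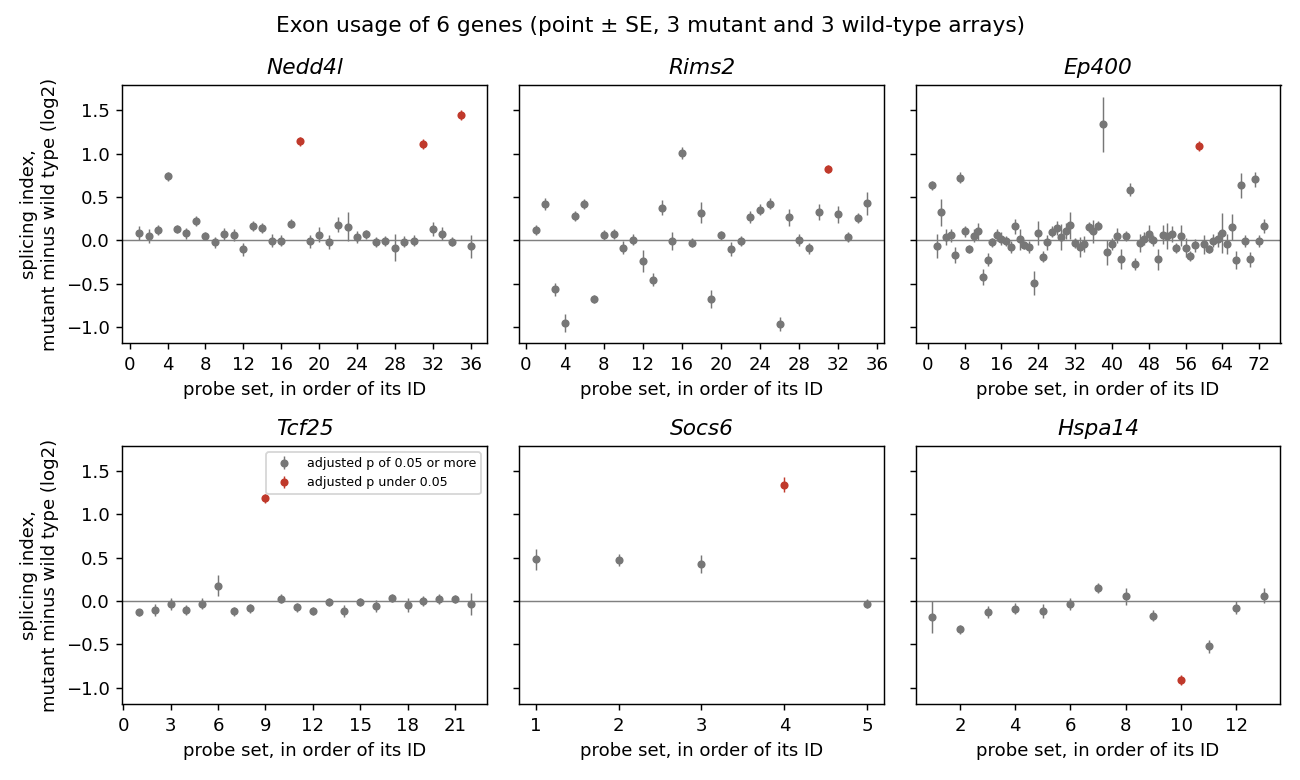
The vertical axis is the mutant minus wild-type splicing index in log2 and the horizontal axis the tested probe sets of a gene in the order of their IDs, which is not their order in the gene. Points are estimates with their SE from 3 mutant and 3 wild-type arrays, and coloured points passed; the 3 coloured Nedd4l probe sets lie between 1.11 and 1.45, and Acvr1 is not drawn.

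The probe sets next in order did not pass. Relative to their genes, the probe sets of Lcor were at 0.90 (adjusted p = 0.0506), Slc8a1 at 1.05, Lrp6 at 0.62, Lrrc58 at 0.88 and Hipk3 at 0.74, and those of Aifm3 at -0.85, Pias4 at -0.88, Asb6 at -0.62, Ppan at -1.06, Radil at -0.57, Mtus1 at -0.87 and Lpp at -0.60 (adjusted p from 0.0553 to 0.0614 for these 11). The Aifm3 probe set was its gene's median on every wild-type array, so its wild-type SD is 0. The Pias4 and Ppan probe sets themselves moved by 0.34 and 0.04, while their genes' median probe sets rose by 1.22 and 1.10. Of the 7 genes with a passing probe set, 3 also changed at the gene level, where 0.746 would be expected by chance among 6702 genes tested both ways (Fisher's exact test, two-sided, p = 0.0303). That test takes no account of probe set number. The index subtracts the gene's own median, so a change of level with unequal probe response can also give a call. No list was enriched for these 7 genes by Fisher's exact test; 1 list, presynaptic release, had an unadjusted p under 0.05, through Rims2 (p = 0.0220, adjusted p = 0.879).

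diffSplice, which sets each probe set against its gene's other probe sets with 1 variance per gene, called 1346 of the same probe sets in 957 genes, 704 higher and 642 lower, including 8 of the 9. On simulated arrays with 200 changed probe sets, 655 of its 817 calls (80.2%) were false, against 0 of 35 for the splicing index, which recovered 34 of 100 changes of 1 and 1 of 100 changes of 0.5 on the log2 scale. That share depends on the number of changes planted and need not hold on the real arrays. Real arrays grouped across genotypes gave 12 to 407 diffSplice calls. The genotype difference adds to the spread within such groups, so these counts are not a rate of false calls either. With diffSplice calls, 3 lists were enriched: cytoskeleton and axon genes, with 12 of 27 genes called (Fisher's exact test, adjusted p = 0.00265), SR proteins, with 10 of 26 (adjusted p = 0.0144), and voltage-gated ion channels, with 10 of 25 (adjusted p = 0.0144). That test takes no account of probe set number, and called genes had a median of 19 tested probe sets against 12 in other genes. Against random lists matched on probe set number no list passed, a test chosen after the result was seen, with permutation adjusted p-values of 0.168 for the cytoskeleton and SR protein lists and 0.230 for the ion channels. No splicing index call was kept with any 1 array left out, where 9508 to 13556 probe sets had an unadjusted p under 0.05.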

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

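Chosen after seeing the data were the tests on transcript clusters only, on the median of a gene's other probe sets, without the microglia lists and on matched lists for diffSplice; the cause of a difference was not tested unless given. Gene-level rows changed, 1342 as reported, numbered 2586 among rows at or above the table median, 2149 with trend and robust eBayes and 2788 at an adjusted p under 0.1; 1066, 1319 and 1342 of these were among the reported ones. Testing transcript clusters only gave 1959, among them all 1070 clusters reported. Leaving out each array gave 76 to 496 gene-level rows, 0 probe sets, 0 exon usage calls in 0 genes, and 17 to 21 lists. Fewer arrays are part of that setting's construction.

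Probe sets changed, 2307 as reported, numbered 13382 at or above the table median and 15561 with trend and robust eBayes. Exon usage calls, 9 in 7 genes as reported, numbered 51 in 31 genes for probe sets at or above the table median, 111 in 68 with the gene-level table value, 163 in 119 with the mean of the probe sets, 207 in 128 with trend and robust eBayes, 1346 in 957 by diffSplice, 161 in 103 with the median of the other probe sets, 100 in 63 at an adjusted p under 0.1 and 14 in 8 without chromosome 11. With no filter on level limma gave 0 in 0 genes, beside 18662 probe sets in 8315 genes at an unadjusted p under 0.05. Lists called, 19 as reported, numbered 0 with an estimated correlation (4 at an unadjusted p under 0.05), 12 by fry and 14 at or above the table median. Lists enriched for exon usage numbered 0 as reported, 3 by diffSplice and 0 by diffSplice against matched lists (4 at an unadjusted p under 0.05).

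The replicate number as a block gave 0 gene-level rows, 0 probe sets and 0 exon usage calls in 0 genes by limma, beside 4787 gene-level rows, 34378 probe sets and 10214 exon usage probe sets in 4205 genes at an unadjusted p under 0.05, and 19 lists. Deviations of same-numbered arrays from their genotype's mean correlated at -0.011, -0.038 and 0.032 over gene-level rows, and wild-type array 1 correlated best with mutant array 2 (0.097). These values gave no sign of pairing by number, but so few arrays cannot exclude it. The block also leaves fewer degrees of freedom for the error, which by itself lowers the counts. None of the 20 named genes, 19 called lists and 20 probe sets changed direction in any setting run: of 284 settings over 20 genes 211 kept their side of the threshold, of 209 over 19 lists 168, and of 335 over 20 probe sets 207, with 61 calls lost and 67 gained. The named genes and probe sets had no overlap of the groups, so leaving out an array could not reverse them. The replicate block and the trend and robust settings leave the log2 change as it is. Constant direction in those settings is therefore no sign of stability. Among lists not called, the mean changed sign for the unipolar brush cell, precursor, oxidative stress and circadian lists under quantile normalization and median centring, and for the hnRNP and ribosomal lists under median centring. Signal over background was not given with the values, so rows near the floor were kept.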

Other observations

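The tests of explanations here were chosen after the result was seen, except the 3 on diffSplice calls, whose predictions were written before their values were seen; the bounds for microglia genes and single probe sets were also set, and revised, after the values were seen. Genes outside the lists and the naming rule, chosen after their values were seen, had changes larger than the spread between arrays. Imp4, a ribosomal RNA processing factor, had the smallest p among named rows that rose, with 9.83 ± 0.03 in wild type and 11.08 ± 0.05 in the mutant (SD, n = 3; limma adjusted p = 0.00200). The helicase Ddx27, which acts in ribosome assembly, rose by 0.64 ± 0.04 (log2, SE), and the DNA repair genes Rad54l and Rad50 by 1.00 ± 0.05 and 0.61 ± 0.05. The adhesion genes Ntng1 and Cntnap4 fell by 0.82 ± 0.05 and by 0.74 ± 0.04, and the kinase Prkcb fell by 0.66 ± 0.05. Each was on one side of the wild type in 3 of 3 mutant arrays.

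The rise of microglia genes is open to several readings. A lower share of neurons would raise other cell types alike, but the 95% intervals over arrays of the oligodendrocyte, precursor and endothelial lists reached no higher than 0.143, against a lower bound of 0.382 for the microglia list. Blood or meninges in the dissection would bring their own transcripts, but the intervals of the blood and meningeal lists reached 0.240 and 0.179 around means of -0.002 and -0.03, under the same bound, so neither accounts for the whole rise; under the earlier bound of 0.2 over arrays this would stay open. More microglial cells, each with the same expression, would raise all markers alike, and the median of P2ry12, Tmem119, Siglech, Cx3cr1 and Csf1r differed by -0.82 from that of the other 16 members (-0.81 over arrays, 95% interval -1.22 to -0.40), which goes against equal expression. The set was grouped after values were seen and members of both sets overlap, with Cx3cr1 (0.70) and Csf1r (0.69) passing and Aif1 (0.16), Ptprc (0.26) and Itgam (0.46) low, and probe response was not tested, so more cells and a change of state cannot be told apart. The microglia list holds microglia and macrophage markers together, so entry of macrophages was not told apart from these readings.

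The 6577 single probe sets in the gene-level table stood apart: 240 were higher and 32 lower in the mutant, with a median change of 0.08, while 680 transcript clusters were higher and 390 lower, with a median of 0.004. The medians differed by 0.074, and over arrays the difference was 0.07 with a 95% interval of 0.014 to 0.125, where an array-wide scale would give 0. Against other probe sets in the same of 10 equal bins of signal, the single probe sets were higher by over 0.02 in 9 bins, with an interval over arrays of 0.013 to 0.105 for the mean of the bins, so signal level does not account for the whole shift; with 0.02 in place of 0, the earlier bound, both readings would stay open. The difference from the clusters was 0.08, 0.09 and 0.05 on the mutant arrays and 0.03, -0.009 and -0.02 on the wild-type arrays. None of the single probe sets has a gene symbol at gene level, and 5363 have none at exon level. A candidate explanation, that single probe sets lie in introns or outside annotated genes, was not tested.

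diffSplice calls were more frequent in genes changed in level: 37.5% of these had a call, against 10.7% of other genes. A larger number of probe sets per gene does not account for it, with an odds ratio of 4.48 (95% interval 3.74 to 5.38) within 10 bins of probe set number, nor does a higher signal, with an odds ratio of 4.89 (4.12 to 5.82) within 10 bins of level. Probe sets at the floor or ceiling of signal would fail to follow their gene, but of 266 calls against their gene's change 29.7% lay in the lowest or highest of 10 bins of level (exact binomial 95% interval 24.3 to 35.6%). Those 2 bins hold 20.0% of all tested probe sets. The highest bin held 21 of the 266 calls, so the ceiling does not account for most of them. The lowest bin held 58 (21.8%). Tested probe sets were already at or above 7.06, so the lowest bin is not the floor of signal. The bins therefore cannot decide whether the floor accounts for calls, and low signal could account for some. In the simulation 15 of the 655 false calls lay in the 200 genes changed as a whole, of 7264 tested. Every probe set of those genes was shifted alike, which cancels against the rest of the gene. That count therefore cannot show whether a change of level with unequal probe response gives calls. False calls could still make up part of the difference, and a link between altered splicing and level stays a hypothesis.

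There are 10 splits of the 6 arrays into 3 and 3, too few for a share under 0.05. Every split but the real one mixes the genotypes, so a genotype difference adds to its within-group spread and lowers its limma counts. Low counts in those splits therefore do not show that the real calls are sound. The real split was the 1 split with as large a count in each of 6 results: 1342 gene-level rows against at most 0 in the others, 2307 probe sets against 0, 9 exon usage calls against 0, in 7 genes against 0, 19 lists against 15, and 1346 diffSplice calls against 407.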
